A study of Mus musculus with 26 samples.

How the data were processed

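The series followed mouse embryonic stem (ES) cells as they were turned into spinal motor neurons in culture. Per the labels' protocols, the cells were seeded on day 0, and 1 uM retinoic acid and 0.25 uM SAG, an agonist of Hedgehog signalling, were added on day 2. DAPT, a gamma-secretase inhibitor that blocks Notch signalling, was added at 5 uM from day 4. A pair of engineered lines carried transgenes switched on by 3 ug/ml doxycycline: an Ngn2 line, induced on day 3, and the NIL line, induced on day 2. Of the 26 samples, 23 were analysed here. The IgG and whole cell extract controls were not used here.

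Isl1, Onecut1 and Lhx3 were mapped by ChIP-exo, in which an exonuclease trims the precipitated DNA up to the bound protein. Isl1 had 2 replicate libraries on day 5 and 2 on day 6, and Onecut1 had 1 library on each of these days. The library labelled Lhx3 was made with a V5 tag antibody from the induced NIL line on day 4, whose label names retinoic acid and doxycycline but no SAG. The name of its deposited file mentions Isl1 in place of Lhx3, so which factor it maps is not settled here, and it is called the library labelled Lhx3 throughout. Ngn2 was mapped by ChIP-seq with a V5 antibody in the induced Ngn2 line on day 4. The coactivator p300 was mapped on days 5 and 6. Acetylated lysine 27 of histone H3 (H3K27ac), a mark of active enhancers and promoters, was mapped on day 4 (2 libraries), day 5 and day 6. Open chromatin was mapped by ATAC-seq on days 2, 4, 5 and 6 and by DNase-seq on day 0. Ribosome-depleted RNA was sequenced on days 0, 4, 5 and 6, with 1 library per day.

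The labels give the RNA of days 0 and 4 to the HBG3 line and that of days 5 and 6 to the iCre line, so the step from day 4 to day 5 holds a change of line as well as of day. A second label field names Ainv15 cells for every sample. The name of the deposited file of the second day 4 H3K27ac library mentions HBG3, while its label says iCre. The labels give no batch. The names of the deposited Isl1 files carry a mark that both day 5 libraries and day 6 replicate 2 share and day 6 replicate 1 does not. That library carries another mark, which the Onecut1 file of day 6 shares and that of day 5 does not, so the class comparisons were also made without day 6 replicate 1.

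The submitters' processing notes name Bowtie 0.12.7, HOMER 4.7.2, STAR and MACS, and the mouse genome build mm9, with no role for each. All coordinates below are mm9 as deposited. The program that made the FPKM is not given in the sources used here. The RNA table holds FPKM (fragments scaled by gene length and library size) made by the authors for 37450 gene IDs, of which 32798 were found in a table of current gene names. Per the file headers, each event list gives the signal assigned to an event as precipitated reads and as scaled control reads, the fold ratio between these, and −log10 q-values and −log10 p-values. The lowest −log10 q in the deposited event lists was 2.00. Each list belongs to 1 library. Peaks of ATAC-seq and H3K27ac, and the Ngn2 and DNase lists, come with a score per peak as deposited by the authors. These scores were used only to describe or rank the peaks of 1 list. The deposited ATAC lists also hold a p-value per peak, which was not used. ATAC peaks had a median width of 100 bp, and the median width of H3K27ac peaks lay between 336 and 479 bp.

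The number of reads per library is not given in the sources used here. For RNA, the lowest FPKM values show how much 1 read was worth in a library relative to the next. The most common ratio, day 4 over day 5, was 1.03 (30.5% of 495 low genes), and day 5 over day 6 was 1.33 (27.2% of 603). For day 0 over day 4 the most common ratio, 0.507, held 12.7% of 537 low genes.

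RNA was compared as differences of log2(FPKM + 1), which understate the change of low genes, among genes at 1 FPKM or more in either library. There are no replicates, so no test was made. A gene is called higher or lower where the difference reached 2-fold. Genes below 1 FPKM in the earlier library enter only by reaching it in the later, which favours calls of higher among them. For each of 22 gene lists, the median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The lists cover stages of motor neuron differentiation, terminal features of neurons, signalling responses, Hox genes, 6 other cell types, stress, and X and Y linked genes. Symbols with more than 1 entry in the table (Isl2, Scn8a and Hoxa3) were left out of the lists because their reads may be split. Sox1, Slc18a3 and Tubb3 were not analysed here, and some members of the lists are not reported by name. Map2 was taken by its gene ID. A value of exactly 0 can be a failed estimate, and no fold is given for it.

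Isl1 events of the 4 libraries were merged into sites. Events were taken by falling −log10 p, and every event within 100 bp of a stronger one joined it. A site was called in a library with an event within 100 bp. The day 5 class holds sites called in both day 5 libraries and in neither of day 6, the day 6 class the converse, and the shared class sites called in all 4. A site carried another factor or mark if a listed event or peak lay within 100 bp (Onecut1, the library labelled Lhx3, ATAC and DNase), 250 bp (Ngn2), 500 bp (p300) or 1000 bp (H3K27ac). Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. The day 6 and day 5 classes were compared by Fisher's exact tests against either direction, with Benjamini-Hochberg adjustment over 15 libraries. These tests treat sites as independent, and the labels do not say that replicates came from separate cultures, so their p-values describe these libraries. The same sites moved by 10 kb in each direction gave the chance level, which was not matched for open chromatin. Whether a feature changed differently from day 5 to day 6 in the 2 classes was tested by permuting the class labels of the sites 100000 times, counting differences of either sign, with adjustment over 4 features. Whole peak lists were compared by overlap of at least 1 bp.

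Genes named in the text were the targets of the ChIP experiments, the 8 largest rises and 8 largest falls at each step among genes at 5 FPKM or more in either library, and up to 4 members of each list with the largest change. Names of unnamed loci, small RNAs, mitochondrial, histone and ribosomal protein genes were left out by the form of the name, which let the small RNA U4atac through. Symbols with more than 1 entry were also left out, an exception made after the table was seen. The 3 sites of each class with the highest mean read strength are named. Lists, classes, windows, tests and alternatives were fixed before the data were examined, with these exceptions. The permutation tests of the change from day 5 to day 6 were chosen after the class shares were seen, as were the comparisons of shared with day 5 sites and the tests of explanations and hypotheses. The removal of RNA values listed at 0 was chosen after the RNA table was seen. No annotation of mm9 was used here, so sites are not assigned to genes.

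Alternatives were a pseudocount of 0.1 FPKM, FPKM rescaled by the median ratio, no filter on low values, other windows and overlaps, lists cut to the same length, and each Isl1 library and each day 4 H3K27ac library left out in turn. The steps were tested on simulated data. All 200, 100 and 150 planted sites of the day 5, shared and day 6 classes were recovered, and none of 2000 single-library events entered a class. Each planted site had an event in every library that defines its class. Missed calls were thus not simulated, and the result checks the steps, not the accuracy of the observed classes. With equal shares in classes of the observed sizes, 5.3% of Fisher's exact tests had p under 0.05. Of 200 lists of 15 genes raised by 1 log2 unit among the 11339 genes of the step from day 4 to day 5, 96.5% lay above the middle 95% of random lists, and of 200 unchanged lists 5.0% lay outside it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1 were used.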

Results

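Expression, transcription factor binding and chromatin were measured along the differentiation of mouse ES cells into spinal motor neurons, from ES cells on day 0 through progenitors on day 4 to the cells of days 5 and 6, which the labels call postmitotic. Isl1, a LIM-homeodomain factor of motor neurons, was mapped in 2 libraries on each of days 5 and 6, and the lists held 2260 and 1079 events on day 5 and 1470 and 1560 on day 6. Onecut1, a factor of the Onecut family, had 23245 events on day 5 and 63488 on day 6. The library labelled Lhx3 listed 1629 events and the Ngn2 library 3184 peaks. The p300 lists held 19398 events on day 5 and 1337 on day 6. H3K27ac lists held between 24353 and 47275 peaks, ATAC lists between 47839 and 85989, and the DNase list of ES cells 9955. RNA, H3K27ac of days 5 and 6, Onecut1, p300, ATAC, DNase, Ngn2 and the library labelled Lhx3 had no replicate libraries.

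The first RNA comparison asked what separates progenitors on day 4 from ES cells. Genes of pluripotency were lower on day 4 in 16 of 17 measured cases, with a list median of −4.37 on the log2 scale. Nanog went from 135.7 to 0.0420 FPKM, Pou5f1 from 168.4 to 0.296, Zfp42 from 117.9 to 0.198 and Dppa5a from 523.9 to 1.79, while Tdgf1 was listed at 241.7 on day 0 and at 0 on day 4. All 13 measured progenitor genes were higher (median 2.95), among them Pax6 (0.151 to 61.5 FPKM), Hes5, a Notch target (0.119 to 83.4), and Sox3 (0.332 to 44.5). Nkx6-1, a ventral patterning factor, was listed at 0 and then at 18.4 FPKM. Neurogenesis and Notch signalling genes were higher in 9 of 10 cases (median 2.48), with the proneural factor Neurog2 going from 0.0483 to 19.7 FPKM and Neurod4 from 0.0185 to 9.28.

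Genes known to respond to the 2 added signals were higher on day 4, with no culture without the signals to compare. All 9 retinoic acid response genes were higher (median 4.23), including Crabp2, a retinoic acid binding protein (2.20 to 456.3 FPKM), and Cyp26a1, which degrades retinoic acid (0.106 to 37.7). All 4 Hedgehog response genes were higher (median 2.54), including Gli1 (0.354 to 11.4) and Ptch1 (7.72 to 59.0). All 12 measured Hox genes of groups 1 to 5 were higher (median 4.34), led by Hoxd4 (0.103 to 51.4) and Hoxb3 (0.0575 to 31.4). Of 24 listed Hox genes of groups 6 to 13, 4 were measured and all 4 were higher, led by Hoxb6 (0.0910 to 33.4). All 24 lay below 1 FPKM on day 0, so a member could be measured only by reaching it on day 4. The 5 lists named here from progenitors to Hox groups 1 to 5 lay at percentiles of 99.99 to 100 among random lists and pluripotency at 0. Motor neuron factors were already detectable, with 5 of 7 members measured and all 5 higher (median 1.52). Isl1 stood at 3.68 FPKM on day 4, Mnx1 at 3.95 and Lhx3 at 2.09. Cell cycle genes differed less, with 15 of 16 within 2-fold and Mki67 higher (14.3 to 39.8). Other genes with the largest differences upward were Mdk, a heparin-binding growth factor (5.78 to 555.9 FPKM), and Nr2f1, a nuclear receptor (0.108 to 34.5). Downward they were L1td1 (76.0 to 0.0320), Mylpf (117.5 to 0.596) and Pfkp (80.8 to 0.481).

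Among terminal neuronal lists on day 4, 2 of 8 cholinergic genes were measured and both were higher (Chrna3 and Chrna4). Higher too were 9 of 15 pan-neuronal genes (median 1.09), with 3 lower, and 6 of 11 axon guidance genes (median 1.28), with 1 lower. Stmn2, a neuronal microtubule regulator, was lower, at 28.0 FPKM on day 0 and 3.59 on day 4, and Gap43 went from 0.711 to 12.4. The 2 measured ion channel genes stayed within 2-fold. Over all 11482 genes, 2219 were at least 2-fold higher on day 4 and 1366 lower, so that 61.9% of the changed genes were higher. The median gene differed by 0.23. After rescaling the libraries to a common median ratio, a shift of 0.27 on the log2 scale, 47.4% of changed genes were higher (1590 against 1762), and the medians of the cell cycle and ion channel lists changed sign, from 0.15 to −0.11 and from 0.01 to −0.27. Of the counts above, 12 of 13 progenitor genes, 7 of 16 pan-neuronal genes and 3 of 4 genes of Hox groups 6 to 13 were then higher.

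The second RNA comparison covered the exit from the progenitor state. Motor neuron transcription factors were higher on day 5 in 6 of 7 cases (median 2.92). Isl1 went from 3.68 to 88.0 FPKM, Lhx4 from 0.797 to 22.8, Lhx3 from 2.09 to 24.1, Mnx1 from 3.95 to 36.5 and Onecut1 from 1.99 to 12.5. Pan-neuronal genes were higher in 17 of 20 cases (median 2.92), among them the microtubule protein gene Map2 (4.14 to 161.4), the RNA-binding protein gene Elavl4 (5.74 to 139.3) and the neurofilament genes Nefl (9.27 to 194.9) and Nefm (0.853 to 35.9). All 6 measured cholinergic genes were higher (median 2.35), including Chat, which makes acetylcholine (0.596 to 8.02), Slc10a4 (0.455 to 13.6) and Chrnb2 (0.783 to 10.5). Axon guidance genes were higher in 14 of 15 cases (median 2.29), with Slit2 going from 11.3 to 406.6 FPKM, Slit3 from 6.15 to 192.2 and Cxcr4 from 14.5 to 149.8. Ion channel genes were higher in 7 of 9 cases (median 1.99), including Cacna2d1 (2.40 to 34.9) and Scn3a (0.474 to 8.08). These 5 lists lay at percentile 100 among random lists.

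All 16 cell cycle genes were lower on day 5 (median −2.33, percentile 0), for example Mcm5 (70.3 to 8.64 FPKM), Birc5 (49.7 to 6.23) and Pcna (196.9 to 31.9). Progenitor genes were lower in 7 of 13 cases (median −1.10, percentile 0.06), with Hes5 at 83.4 and then 1.90 FPKM, Pax6 at 61.5 and 3.42, and Sox3 at 44.5 and 3.44. Neurogenesis genes were still higher in 5 of 11 cases (median 0.74, percentile 99.7), including Neurod4 (9.28 to 44.2) and Dll3 (5.87 to 20.2). Hedgehog response genes were lower in 3 of 4 cases (median −1.14), with Gli1 at 11.4 and then 0.404. The retinoic acid list went both ways: 5 of 9 genes were higher, such as Cyp26b1 (6.31 to 64.3), and 2 were lower, Cyp26a1 (37.7 to 5.04) and Crabp2 (456.3 to 95.04). Hox genes of groups 1 to 5 were higher in 2 of 12 cases, Hoxa5 (25.8 to 80.0) and Hoxc5 (5.36 to 14.1), and the 5 measured genes of groups 6 to 13 stayed within 2-fold. The 2 pluripotency genes still measured were Lin28a (41.0 to 32.4) and Dppa5a (1.79 to 0.281).

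Further genes with the largest differences upward from day 4 to day 5 were Cntn2, an axonal adhesion molecule (1.72 to 110.6 FPKM), Sncg (2.39 to 90.1) and Myt1 (1.71 to 58.6). Lars2 (1.28 to 59.6, then 3.77 on day 6) and Ftl2 (1.67 to 75.4) also appear, the latter uncertain because ferritin light chain genes have near-identical copies. Downward they included Baiap2l1 (31.5 to 0.235), Stra8 (24.4 to 0.0985), Sfrp2, a secreted Wnt modulator (47.7 to 1.80), and the metallothionein genes Mt1 (85.2 to 2.76) and Mt2 (52.9 to 1.93). G3bp2 was listed at 32.6 and then at 0. Hprt, a purine salvage gene used in most cells, went from 21.8 to 0.2996 FPKM between the libraries of the HBG3 and iCre lines and stood at 55.4 on day 0 and 0.311 on day 6. Over 11339 genes, 1308 were higher and 1668 lower, and the rescaled values, a shift of −0.15, gave 1493 and 1302. Rescaling left 15 cell cycle genes lower in place of 16, 2 Hedgehog response genes in place of 3 and 6 progenitor genes in place of 7, with Fabp7, named after its value was seen, higher. It turned the median of Hox groups 1 to 5 from −0.08 to 0.06. The step cannot be separated from the change of line.

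The third RNA comparison, within the iCre line, followed the neurons from day 5 to day 6. Lhx3 went from 24.1 to 3.90 FPKM and Lhx4 from 22.8 to 10.4, the 2 of 7 motor neuron factors that were lower. Isl1 (88.0 to 116.5), Onecut1 (12.5 to 14.0) and Mnx1 (36.5 to 22.0) stayed within 2-fold, as did Ep300, which encodes p300 (13.7 to 12.6). Neurogenesis and Notch signalling genes were lower in 9 of 12 cases (median −1.89, percentile 0), led by Neurog2 (29.9 to 0.899), Neurod4 (44.2 to 2.26) and Dll3 (20.2 to 3.33). The 1 higher member was Neurog3 (0.152 to 3.42), named after its value was seen. All 16 cell cycle genes were lower again (median −2.19, percentile 0), such as Top2a (37.8 to 3.07) and Ccnb1 (17.5 to 1.474), and progenitor genes in 7 of 13 cases (median −1.01), such as Olig2 (17.3 to 0.9496) and Notch1 (14.3 to 0.715).

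Pan-neuronal genes were higher in 13 of 22 cases and lower in none (median 1.16, percentile 100), with the intermediate filament gene Prph going from 8.16 to 132.1 FPKM, Uchl1 from 44.0 to 215.3, Nefl from 194.9 to 800.0 and the tau gene Mapt from 15.8 to 64.0. Ion channel genes were higher in 5 of 11 cases (median 1.00, percentile 100), among them the sodium channel genes Scn3b (3.99 to 29.5), Scn2a1 (0.961 to 8.81) and Scn3a (8.08 to 42.3). In the cholinergic list, 2 of 8 genes were higher, Ache, which breaks down acetylcholine (0.379 to 6.9996), and the choline transporter gene Slc5a7 (0.519 to 6.05), and 1 was lower, Chrna3 (19.9 to 6.80). Axon guidance genes went both ways, with 5 of 15 higher, such as Unc5c (1.86 to 9.54), and 2 lower, Cxcr4 (149.8 to 20.6) and Robo2 (49.4 to 22.5). Of the Hox genes of groups 1 to 5, 4 of 13 were lower, all of the Hoxb cluster, such as Hoxb4 (34.6 to 9.16), and of groups 6 to 13, 2 of 5 were lower, Hoxb6 (53.5 to 15.5) and Hoxb8 (15.1 to 4.03). Hedgehog response genes were lower in 2 of 3 cases, such as Ptch1 (28.3 to 6.85), and retinoic acid response genes in 3 of 9, such as Cyp26b1 (64.3 to 9.099).

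Among other large changes, Aldh1a2, which makes retinoic acid, went from 0.875 to 33.4 FPKM, Ptn from 1.17 to 31.3, Slc44a5 from 3.87 to 41.7, Rbms3 from 2.80 to 30.5, Ly6h from 1.17 to 16.0 and Btbd17 from 56.3 to 5.25. Camsap1 and U4atac were listed at 0 on day 5, and Peg10 and Evi5l at 0 on day 6. Over 11164 genes, 734 were higher and 691 lower (51.5% of the changed genes higher). A pseudocount of 0.1 FPKM gave 1127 and 1077. Rescaling, a shift of −0.15, gave 62.1% higher (917 against 559), and with it 1 motor neuron factor, Lhx3, was at least 2-fold lower. Lower genes then numbered 5 of 13 in the progenitor list, 3 of 13 in Hox groups 1 to 5, 1 of 15 in axon guidance, without Robo2, and 2 of 9 in the retinoic acid list, where Crabp2 was higher. Pan-neuronal genes were then higher in 15 cases and ion channel genes in 7.

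**Figure D1:**
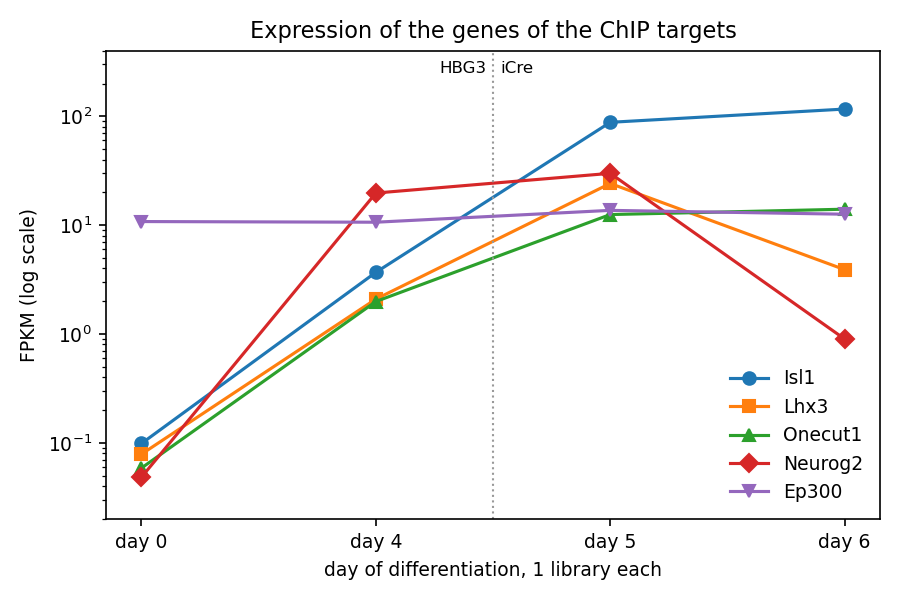
FPKM (log axis) of the genes encoding the ChIP targets on days 0, 4, 5 and 6, 1 library per point; the dotted line marks the change from the HBG3 to the iCre line in the labels. Isl1 reaches 116.5 FPKM on day 6, while Lhx3 goes from 24.1 to 3.90 and Neurog2 from 29.9 to 0.899 between days 5 and 6.

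**Figure D2:**
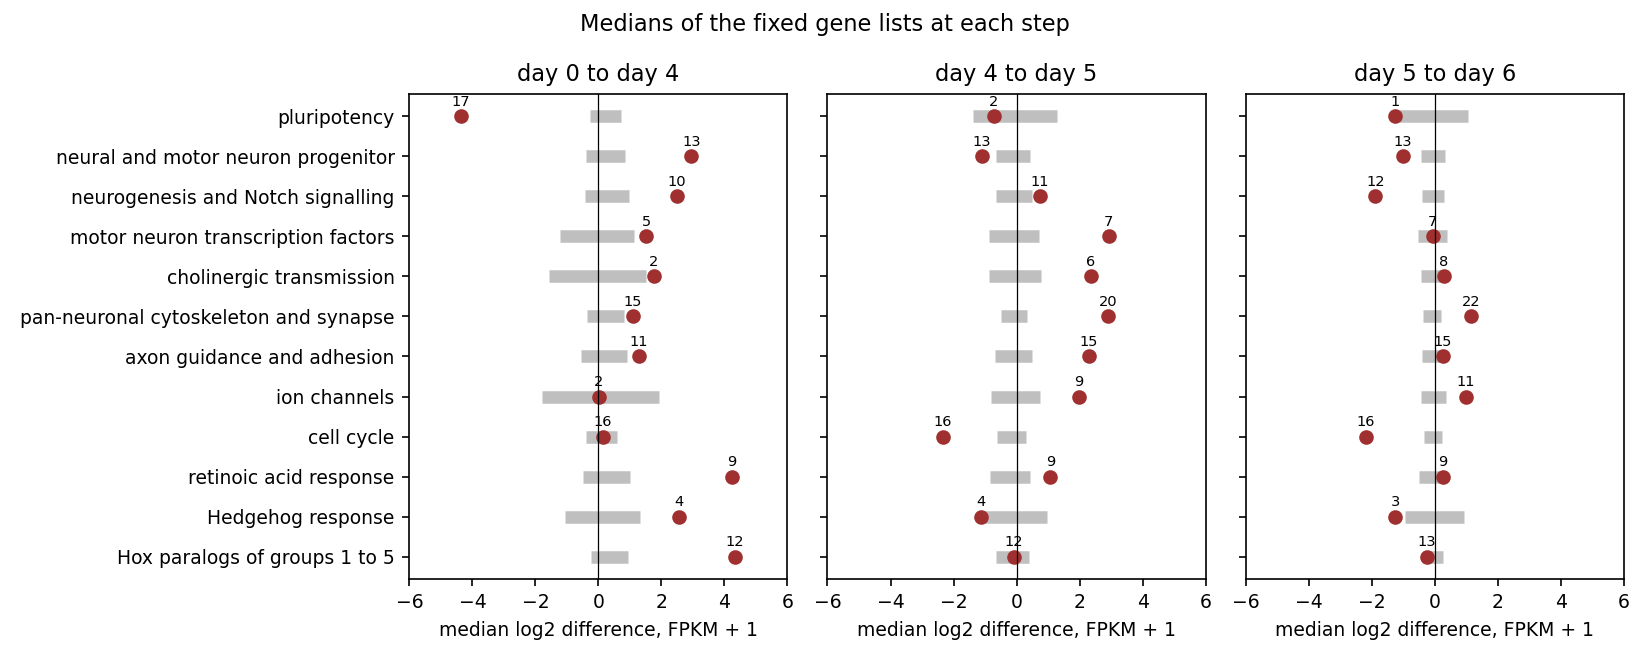
Median log2 difference of FPKM + 1 (x axis) of 12 gene lists (y axis) at each step; points are list medians, the numbers count measured genes, and grey bars hold the middle 95% of random lists. Cell cycle genes lie at 0.15, −2.33 and −2.19 at the 3 steps.

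Markers of other cell types were few. The V0, V1 and dorsal interneuron list had no member at 1 FPKM on days 0 and 4, and on day 5 it had 2 of 13, Lhx1 (2.21 FPKM) and Pou4f1 (2.03). The V2 interneuron list held 1 measured gene, Sox21, at 18.8 FPKM on day 4 and 1.62 on day 5. In the V3 and floor plate list, Nkx2-9 stood at 14.3 FPKM on day 4 and 3.26 on day 5, Nkx2-2 was listed at 0 on day 4 and at 8.86 on day 5, and Sim1 and Shh stood at 3.24 and 3.23 on day 6. Cranial motor neuron genes were higher on day 5 in 3 of 3 cases, among them Tbx20, which stood at 0.0316 FPKM on day 4, 2.41 on day 5 and 10.4 on day 6. Of the glial list, 3 of 9 genes were measured on day 5, where Mbp stood at 11.5 FPKM and Slc1a3 at 0.339. Of the mesoderm, endothelium and blood list 3 of 3 measured genes were lower on day 4, such as Pecam1 (13.9 to 0.194), and none reached 1 FPKM from day 4 on. Of the endoderm and epithelium list 3 of 3 were lower on day 4, such as Epcam (91.0 to 3.19), and Krt8 stood at 1.57 FPKM on day 6. Stress and apoptosis genes were lower in 4 of 8 cases on day 5, such as Chac1 (8.13 to 1.49), or in 1 after rescaling, and the 6 measured on day 6 were within 2-fold.

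The Isl1 maps asked whether the factor stays at the same sites from day 5 to day 6. The 4 libraries gave 4605 sites, of which 525 were called in both day 5 libraries and 448 in both day 6 libraries. Of the day 5 sites, 66 (12.6%, 95% interval 9.86 to 15.7) were also called in both day 6 libraries, and 175 (33.3%) in at least 1. The classes held 350 day 5 sites, 66 shared sites and 310 day 6 sites. Replicates overlapped by 19.5% of their union on day 5 and by 18.5% on day 6, against 6.04% to 12.8% for the 4 pairs of libraries of different days. Grouping the libraries by day left 660 sites bound in 1 pair and not the other, and the other 2 splits left 177 and 88 (exact permutation p = 0.333, the smallest that 3 splits allow). Agreement between replicates was limited, since 3433 sites were called in 1 library alone. The share of day 5 sites kept depended on the libraries, from 5.04% without day 5 replicate 2 and 8.65% without day 5 replicate 1 to 17.3% without day 6 replicate 2 and 28.5% without day 6 replicate 1. The day 5 class then held 713 sites without day 5 replicate 1 and 1807 without day 5 replicate 2, and the day 6 class 1065 and 1146 without day 6 replicates 1 and 2.

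The strongest day 5 sites lay at chromosome 4 position 73150294 (174.4 and 104.4 reads in the 2 libraries), chromosome 11 position 35357523 (121.5 and 63.1) and chromosome 1 position 53997594 (111.1 and 61.2). The strongest shared sites lay at chromosome 11 position 35357918, chromosome 5 position 12365945 and chromosome 13 position 47636255, all with an event of the library labelled Lhx3 and with p300 on day 5. The first of them lay in the same region as the second day 5 site. The strongest day 6 sites lay at chromosome 9 position 46777267 (199.6 and 100.5 reads), chromosome 3 position 80562866 (182.0 and 57.8) and chromosome 13 position 116738653 (41.1 and 197.3). The latter 2 had Onecut1 on both days, and none of the 3 had an event of the library labelled Lhx3. Mean read strength had a median of 27.1 in the day 5 class and 22.3 in the day 6 class. Shared sites were stronger, with a median of 44.2 in the day 5 libraries and 37.8 in those of day 6. The day 5 and day 6 classes thus hold weaker sites, and missed calls on the other day stay open for them.

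The next comparisons asked which factors lie at the Isl1 sites of each day. Events of the library labelled Lhx3 lay at 117 of 350 day 5 sites (33.4%, 28.5 to 38.6) and 33 of 66 shared sites (50.0%, 37.4 to 62.6), but at 9 of 310 day 6 sites (2.90%, 1.34 to 5.44). The day 6 class was below the day 5 class by Fisher's exact test (odds ratio 0.0598, p = 1.1e-26, adjusted 5.5e-26). If this library maps Isl1, as its file name has it, these shares compare Isl1 of the induced line with Isl1 of days 5 and 6. Ngn2 peaks of day 4 lay at 33 day 5 sites (9.43%), 3 shared sites and 1 day 6 site (0.323%; odds ratio 0.0312, Fisher's exact p = 9.0e-09, adjusted 1.4e-08). Onecut1 showed the opposite order. On day 6 its events lay at 174 day 6 sites (56.1%, 50.4 to 61.7), 25 shared sites (37.9%, 26.2 to 50.7) and 48 day 5 sites (13.7%, 10.3 to 17.8; odds ratio 8.02, 5.43 to 12.0, Fisher's exact p = 1.3e-31, adjusted 2.0e-30). On day 5, before Isl1 was listed at the day 6 class, Onecut1 already lay at 112 of its sites (36.1%, 30.8 to 41.7) and at 49 day 5 sites (14.0%; odds ratio 3.47, Fisher's exact p = 3.7e-11, adjusted 7.0e-11). At sites moved by 10 kb the shares of Onecut1, Ngn2 and the library labelled Lhx3 were at most 1.0%. At most 1.43% of the moved sites of any class held an ATAC peak, so this is not the level of open regions.

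The change between days 5 and 6 was compared by a test chosen after the class shares were seen. Onecut1 was gained at 67 day 6 sites and lost at 5, a change of 20 percentage points, against 19 gained and 20 lost at day 5 sites (difference 20.3 points, permutation p = 1e-05, the smallest that can be reached, adjusted 1e-05). With the libraries that share a name mark, that is without Isl1 day 6 replicate 1, the class difference for Onecut1 on day 6 was 26.7 percentage points in place of 42.4, for Onecut1 on day 5 it was 9.25 in place of 22.1, and for the library labelled Lhx3 −27.5 in place of −30.5. Without Isl1 day 5 replicate 2 the latter difference was −9.20. Without Isl1 day 6 replicate 2, which leaves the day 6 library with the mark of Onecut1 day 6, the Onecut1 differences were larger than without replicate 1. They were 39.0 points on day 6 and 16.4 on day 5. The direction was the same each time and p stayed under 0.05.

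The p300, ATAC and H3K27ac lists asked when the sites were active. On day 5, p300 lay at 163 day 5 sites (46.6%, 41.2 to 52.0), 54 shared sites (81.8%, 70.4 to 90.2) and 121 day 6 sites (39.0%, 33.6 to 44.7), and the day 6 and day 5 classes did not differ past the threshold (Fisher's exact p = 0.059, adjusted 0.063). This call depended on the lists used. The class difference of −7.54 points was −4.55 (Fisher's exact p = 0.028) with 1337 events on each day. Without 1 Isl1 library it was −20.0 (day 6 replicate 1, Fisher's exact p = 4.4e-12), −17.1 (day 6 replicate 2, p = 5.5e-10), 9.07 (day 5 replicate 2, p = 0.0014) or 3.72 (day 5 replicate 1, p = 0.26). Between the days the p300 share changed by −45.1 points in the day 5 class and −18.7 in the day 6 class, a difference of 26.4 points (permutation p = 1e-05) that was 9.36 without day 5 replicate 2 and 14.1 without day 5 replicate 1. With 1337 events on each day the day 5 class changed by −8.29 points and the day 6 class by 15.2, so the direction in the day 6 class depended on list length. On day 6, p300 lay at 63 day 6 sites (20.3%, 16.0 to 25.2) and 14 shared sites (21.2%), and at 5 day 5 sites (1.43%, 0.465 to 3.30; odds ratio 17.5, Fisher's exact p = 5.6e-17, adjusted 1.7e-16). That class difference of 18.9 points was 10.5 without Isl1 day 6 replicate 1 and 10.2 without day 6 replicate 2.

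Open chromatin was present at few of these sites early. DNase peaks of ES cells lay at 0 of 350 day 5 sites, with an exact interval up to 1.05%, and at 2 day 6 sites (Fisher's exact p = 0.22, adjusted 0.22). On day 2, 20 day 5 sites (5.71%) and 6 day 6 sites (1.94%) held an ATAC peak (Fisher's exact p = 0.015, adjusted 0.018). This difference of −3.78 points was −1.83 (Fisher's exact p = 0.13) without Isl1 day 6 replicate 2 and −2.14 (p = 0.082) with ATAC lists of the same length. On day 4, 74 day 5 sites (21.1%, 17.0 to 25.8) were open and 15 day 6 sites (4.84%, 2.73 to 7.86; odds ratio 0.190, Fisher's exact p = 2.6e-10, adjusted 4.3e-10). The difference of −16.3 points was −9.72 without day 6 replicate 2 and −10.3 without day 5 replicate 1. On day 5 both classes were largely open, with 285 day 5 sites (81.4%, 76.9 to 85.4), 59 shared sites (89.4%) and 201 day 6 sites (64.8%, 59.2 to 70.1; Fisher's exact p = 1.6e-06, adjusted 2.2e-06). This day 5 difference of −16.6 points rested on both day 5 libraries: it was −1.64 (Fisher's exact p = 0.63) without day 5 replicate 1 and 2.56 (p = 0.39) without day 5 replicate 2, −32.2 and −27.1 without day 6 replicates 1 and 2, and −9.78 with equally many events from each Isl1 library. By day 6, 155 day 5 sites (44.3%, 39.0 to 49.7) were open, against 57 shared sites (86.4%) and 267 day 6 sites (86.1%, 81.8 to 89.8; odds ratio 7.79, Fisher's exact p = 2.0e-30, adjusted 1.5e-29). The last difference, 41.8 points, was 28.4 and 27.3 without day 6 replicates 1 and 2.

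H3K27ac came to the day 6 class late. It lay near 14 and 9 of the 310 day 6 sites in the 2 libraries of day 4 (4.52% and 2.90%), near 49 on day 5 (15.8%, 11.9 to 20.4) and near 261 on day 6 (84.2%, 79.6 to 88.1). Of the day 5 class, 90 and 42 sites had the mark on day 4 (25.7% and 12.0%), 185 on day 5 (52.9%, 47.5 to 58.2) and 199 on day 6 (56.9%, 51.5 to 62.1). Shared sites had it in 38 of 66 cases on day 5 (57.6%) and 64 on day 6 (97.0%). The classes differed in all 4 libraries (Fisher's exact p = 7.7e-15 and 7.6e-06 on day 4, 4.3e-24 on day 5 and 1.1e-14 on day 6; adjusted 1.9e-14, 9.5e-06, 1.6e-23 and 2.3e-14). The day 6 list was longer, and with lists of the same length 52.6% of day 5 sites had H3K27ac on day 5 and 35.4% on day 6. Counting a site only when it lay inside the peak left no class difference past the threshold, with Fisher's exact p = 0.095 and 0.10 on day 4, 0.22 on day 5 and 0.25 on day 6. The differences of −37.0 points on day 5 and 27.3 on day 6 were −20.2 without day 5 replicate 2, −23.6 without day 5 replicate 1, and 16.6 and 17.0 without day 6 replicates 1 and 2. The day 4 difference of −9.10 in the second library was −3.50 without day 6 replicate 2. At sites moved by 10 kb the H3K27ac share reached 10.9% in the day 5 class, 18.2% in the shared class and 10.5% in the day 6 class, each on day 6.

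**Figure D3:**
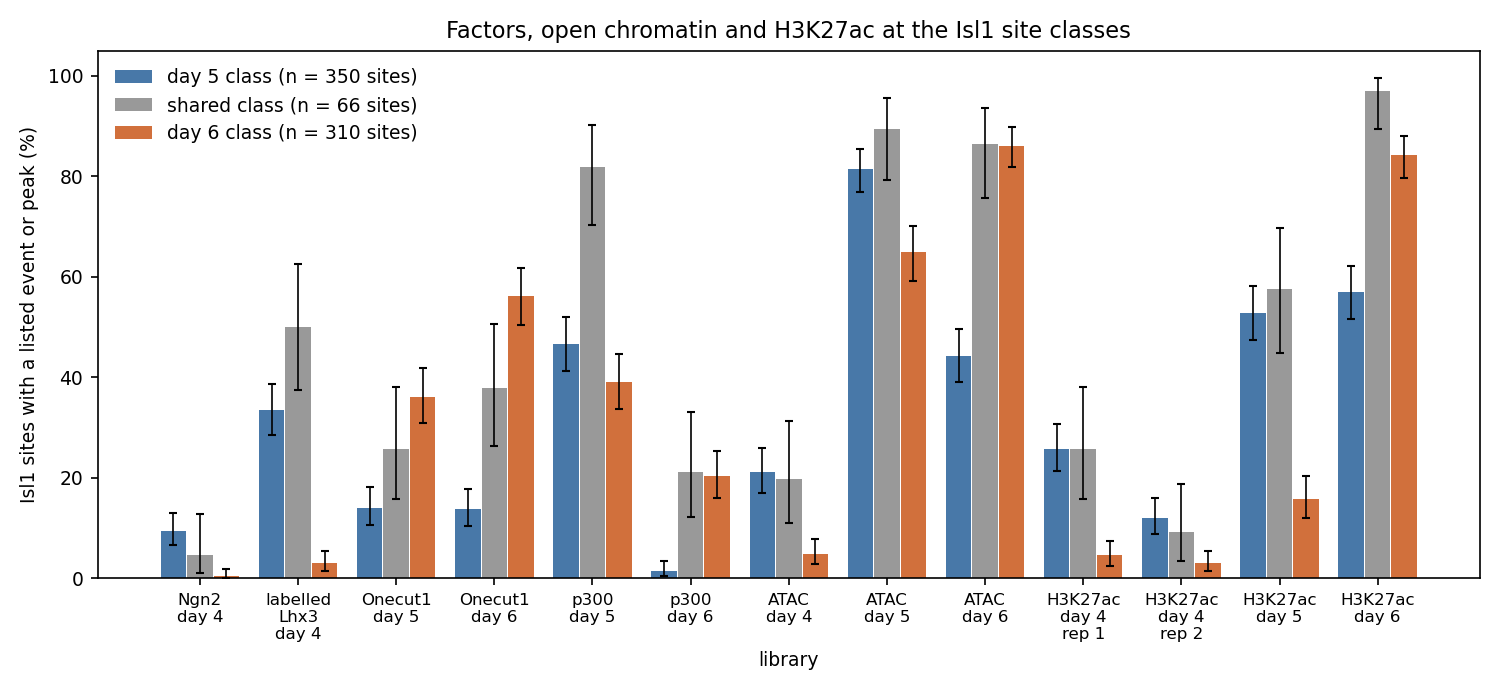
Share of Isl1 sites (y axis, percent) in the day 5, shared and day 6 classes that carry an event or peak of each library (x axis), with exact 95% intervals. Onecut1 on day 6 lies at 13.7% of the day 5 class and 56.1% of the day 6 class, and the library labelled Lhx3 at 33.4% and 2.90%.

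Across whole lists, 16380 of the 23245 Onecut1 events of day 5 (70.5%, 69.9 to 71.1) had a day 6 event within 100 bp, and 25.4% of the 63488 day 6 events had a day 5 event. With as many events on each day, strongest first, the shares were 47.8% and 45.7%. At positions moved by 10 kb 0.602% of day 5 events met a day 6 event. Of the p300 events of day 5, 693 of 19398 (3.57%) had a day 6 event within 500 bp, and 594 of the 1337 day 6 events (44.4%, 41.7 to 47.1) had a day 5 event. With 1337 events on each day the share was 6.21% either way.

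The smallest share of open regions was kept from day 2 to day 4. Of 85989 ATAC peaks on day 2, 27408 (31.9%, 31.6 to 32.2) overlapped a peak of day 4, and 58581 did not. From day 4 to day 5, 28758 of 47839 peaks (60.1%, 59.7 to 60.6) were kept, and 26373 of the 55131 peaks of day 5 (47.8%) were gained. From day 5 to day 6, 34787 peaks (63.1%, 62.7 to 63.5) were kept, 20344 were lost and 17858 of 52645 (33.9%) were gained. H3K27ac peaks of day 4, merged over both libraries, numbered 32405, of which 14745 (45.5%, 45.0 to 46.1) overlapped a day 5 peak. The 2 day 4 libraries overlapped in 69.9% and 85.9% of their peaks. From day 5 to day 6, 16216 of 24525 H3K27ac peaks (66.1%, 65.5 to 66.7) were kept, and 33333 of the 47275 day 6 peaks (70.5%) were gained, or 52.4% with lists of the same length. These are 1 library per day apart from H3K27ac on day 4, and no test was made.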

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

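The permutation tests of the change from day 5 to day 6, with their alternatives, were chosen only after the class shares were seen, and the tests of explanations were set out before their own results were seen. For 4 features the change from day 5 to day 6 differed between the day 6 and day 5 classes of Isl1 sites when the class labels were permuted. The differences, day 6 class minus day 5 class, were 20.3 percentage points for Onecut1, 26.4 for p300, 64.4 for H3K27ac and 58.4 for ATAC peaks, each with permutation p = 1e-05, the smallest that can be reached. The ATAC share changed by −37.1 points in the day 5 class and by 21.3 in the day 6 class. Counting only sites inside a H3K27ac peak left 5.25 points for that mark (permutation p = 0.086).

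Onecut1 lay at a larger share of the day 6 class than of the day 5 class. Accessibility on day 6 does not account for all of it: among sites with an ATAC peak on day 6, Onecut1 lay at 153 of 267 day 6 sites and 28 of 155 day 5 sites (odds ratio 6.06, 3.71 to 10.2). The longer Onecut1 list of day 6 does not either, since as many events as on day 5 gave an odds ratio of 9.52 (6.30 to 14.6). Over 3 strata of Isl1 reads the Mantel-Haenszel odds ratio was 9.18 (6.18 to 13.7). Each class was ranked by the reads of its own day's libraries, so the strata cannot exclude read strength. Because Onecut1 was listed at 36.1% of the day 6 class on day 5, a candidate explanation is that Isl1 moves to regions Onecut1 already holds. Absence from the day 5 lists does not show that Isl1 was absent, since 3433 of 4605 sites were called in 1 library alone. Isl1 bound on day 5 but not called therefore stays open as well. The design gives no loss of Onecut1, so the hypothesis of a move and a common upstream cause stay open. The shared name mark of Onecut1 day 6 and Isl1 day 6 replicate 1 leaves a batch effect partly open. The class difference was 26.7 points without that replicate and 39.0 without day 6 replicate 2.

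The day 5 class lost p300 more than the day 6 class did. The day 6 list is the shorter, but with 1337 events on each day the difference was 23.5 points (permutation p = 1e-05), as the day 5 class went from 9.71% to 1.43% and the day 6 class from 5.16% to 20.3%. The strongest event of day 5 held 2283 reads and that of day 6 held 147, so a weaker precipitation on day 6 stays open for the lower number of p300 events, though it would have to act on the classes unequally to give this difference. The size rests on the Isl1 libraries, at 9.36 points without day 5 replicate 2 and 14.1 without day 5 replicate 1.

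With all listed peaks H3K27ac did not fall at the day 5 class from day 5 to day 6 (a change of 4.0 points, −2.0 to 10.0), while the ATAC share did. List length bears on this. With lists of the same length H3K27ac changed by −17.1 points (−22.9 to −11.7), so the lack of a fall depended on the longer day 6 list. The interval includes −18.6, the bound set beforehand, which lies midway between no change and the ATAC change of −37.1. Whether the mark outlasts open chromatin was therefore left undecided. Peaks lying beside the site stay open too, since only 3.14% of these sites lay inside a peak on day 5, so that the change inside peaks, 15.7 points (12.0 to 19.7), could not have shown such a loss. Without the 18 sites that had an Isl1 day 6 event within 2000 bp the change with all listed peaks was 3.61 points (−2.41 to 9.64). Neighbouring Isl1 sites thus do not account for the lack of a fall with all listed peaks.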

How the results depend on the processing

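The removal of RNA values listed at 0 and the tests of the change from day 5 to day 6 between classes, with their alternatives, were chosen only after the result was seen, and the other alternatives here were chosen before. No paired analysis was possible because the lists hold no value for a site that was not called, and apart from Isl1 no measurement has 2 libraries on both days of a step. Of 130 values of 19 class comparisons under an alternative, 117 kept their direction or their place short of the threshold, 8 no longer passed it, 3 came to pass it and 2 turned. Of 82 values of 24 other results, 38 stayed within their interval or within 1.5 times. These include the RNA counts with no filter on low values, which could not change. With 1 FPKM added, a 2-fold difference already needs at least 1 FPKM in the higher library. The RNA counts moved beyond 1.5 times in 1 case, with a pseudocount of 0.1 FPKM from day 5 to day 6 (1127 higher and 1077 lower). Rescaling moved no count that far but turned which direction was the more frequent at the earlier steps. From day 0 to day 4 it gave 1590 higher and 1762 lower in place of 2219 and 1366. From day 4 to day 5 it gave 1493 and 1302 in place of 1308 and 1668.

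Leaving out each Isl1 library in turn gave 5.04% to 28.5% for day 5 sites shared with day 6 and 6.51% to 24.4% for day 6 sites shared with day 5. The day 5 class then held 374 to 1807 sites and the day 6 class 338 to 1146, because fewer libraries then define a class. The class difference was −20.0 to 9.07 points for p300 on day 5 (reversed, Fisher's exact p = 0.0014, without day 5 replicate 2), −3.64 to −1.83 for ATAC on day 2 and −32.2 to 2.56 for ATAC on day 5 (reversed, p = 0.39, without day 5 replicate 2). With lists of the same length p300 on day 5 differed by −4.55 points (Fisher's exact p = 0.028) and ATAC on day 2 by −2.14. Inside the peak, H3K27ac differed by −2.60 and −2.39 on day 4, −1.53 on day 5 and 3.72 on day 6, and its change by 5.25. H3K27ac peaks had median widths of 336 to 479 bp, so few sites lie inside one, and beyond that the cause was not tested.

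For whole lists, Onecut1 events had a partner within 50 bp in 68.9% of day 5 and 24.4% of day 6 cases, and with equally many events in 47.8% and 45.7%, and p300 events in 6.21% on either day. An overlap of at least 0.5 of the shorter peak gave 25.5%, 48.4% and 51.3% of ATAC peaks kept at the 3 steps and 54.1%, 58.0% and 46.3% gained, and equally long lists gave 47.1%, 56.6% and 65.5% kept and 52.9%, 43.4% and 34.5% gained. For H3K27ac the larger overlap gave 44.7% and 64.97% kept and 31.6% and 70.9% gained at the 2 steps, and equally long lists 48.3% and 57.8% kept and 33.6% and 52.4% gained. Leaving out a day 4 library gave 48.9% to 52.0% kept and 32.1% to 40.5% gained. The number of reads per library, which limits what can be called, is not given in the sources used here.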

Other observations

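The comparisons of shared with day 5 sites were chosen only after the class shares were seen, and the other tests of hypotheses in this part were set out before their own results were seen. Ngn2 peaks of day 4 were most often open on day 4 among the 4 days with ATAC data. Of 3184 peaks, 28.5% held an ATAC peak within 250 bp on day 2, 75.5% on day 4, 62.2% on day 5 and 29.9% on day 6, against at most 2.36% at positions moved by 10 kb. Over the same days Neurog2 RNA stood at 19.7 FPKM on day 4, 29.9 on day 5 and 0.899 on day 6. Most Onecut1 events lay outside listed open chromatin. Of the events present on both days 21.8% had an ATAC peak within 100 bp on day 5 and 26.0% on day 6, and of the 47377 events of day 6 without a day 5 event 7.46% and 11.2%.

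Shared Isl1 sites carried p300 on day 5 in 54 of 66 cases, against 163 of 350 day 5 sites (Fisher's exact p = 8.1e-08), and the Mantel-Haenszel odds ratio over 3 strata of Isl1 read strength was 4.07 (2.06 to 8.02, p = 4.2e-05). Onecut1 lay at 25.8% and 14.0% on day 5 (Fisher's exact p = 0.026), while ATAC peaks, at 89.4% and 81.4%, did not differ past the threshold (Fisher's exact p = 0.15). Events of the library labelled Lhx3, from day 4, lay at 50.0% of shared and 33.4% of day 5 sites (odds ratio 1.99, Fisher's exact p = 0.012). With read strength held apart the odds ratio was 1.19 (0.674 to 2.10), so a link between these events and persistence beyond strength may or may not be there. At shared sites events of this library and Onecut1 of day 6 lay together in 10 of 66 cases, the former alone in 23, Onecut1 alone in 15 and neither in 18. In the day 6 class neither was listed at 133 of 310 sites.

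Many day 6 sites were open on day 5, before Isl1 was listed there. A hypothesis that Onecut1 goes with this early opening was tested within the class: 83 of 112 sites with Onecut1 on day 5 had an ATAC peak on day 5, against 118 of 198 without (odds ratio 1.94, 1.14 to 3.36, Fisher's exact p = 0.013). The values are consistent with it, though which came first cannot be read from 1 day. A second hypothesis, that Onecut1 goes with p300 at day 6 sites, was left undecided: p300 lay at 42 of 174 sites with Onecut1 on day 6 and 21 of 136 without (odds ratio 1.74, 0.944 to 3.28, Fisher's exact p = 0.065). H3K27ac on day 6 was near 83.3% and 85.3% of these sites.

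The highest ATAC scores fell in the same places on every day. The regions starting at chromosome 2 position 98507237 and at chromosome 1 position 24619905 or 24619906 held the highest and second scores of all 4 lists, between 455.8 and 823.5 times the median of their list. Whether scores so far above the median reflect open chromatin was not tested, and they are not read as such here. The Y-linked genes Uty and Ddx3y stood at 4.20 and 2.41 FPKM on day 4 and at 1.55 and 1.06 on day 5, while Eif2s3y, also on Y, stood at 4.41 and 4.97. These 3 genes were the only measured members of the X and Y list, so no X-linked gene entered its median. That median was −0.80 from day 0 to day 4, −0.73 from day 4 to day 5 and −0.06 from day 5 to day 6. After rescaling the values were −1.01, −0.62 and 0.01.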
